A study of Mus musculus with 4 samples.

How the data were processed

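RNA was extracted from brain hemispheres of adult female CFW mice, an outbred laboratory strain, and the RNA of 2 or 3 mice was pooled into 1 sequencing library per treatment group, per the labels' protocols. The submitters' processing notes name CASAVA, FastQC 0.10.1, Trimmomatic 0.27, TopHat2 2.0.4, Cufflinks 2.1.1, Cuffdiff 2.2.1 and Cuffnorm, and the mm10 genome build. The annotation and the settings of these tools are not given in the sources used here. The deposited table gives FPKM values, per its name, with 4 value columns headed A_0, B_0, C_0 and D_0. None of the 4 column names occurs as a name in any sample's title, description, source name or characteristics. A column was to be used only where its name matched a sample, and never by its position or its values. All 4 value columns were therefore left out, and every expression comparison planned before the data were examined was not run. No expression level, fold change, depth or p-value is given.

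Only the first column of the table, which holds Ensembl mouse transcript identifiers, was analysed. Each identifier was matched to the comprehensive GENCODE mouse release 21 annotation of the reference chromosomes, after version suffixes were removed from the annotation's transcript identifiers. The annotation uses the GRCm38 assembly, the assembly that mm10 names. Gene symbols, gene types and coordinates come from that annotation. It may differ in release from the one the authors used. The 32 gene lists had been fixed before the data were examined, and a member was counted as present when at least 1 of its transcripts had a row. The ribosomal protein, mitochondrially encoded and histone lists were fixed as symbol patterns, and their members were taken from the GENCODE annotation. In the other lists, symbols were matched as spelled, so that an older or newer symbol of the same gene counts as absent. For named genes, the rule fixed in advance was to rank genes by their expression differences. It could not be applied, except that it names some genes in any case. These are the estrogen receptors Esr1, Esr2 and Gper1, the progesterone receptor Pgr, and the Y-linked genes. The Y-linked genes were meant to check that the libraries are female, which needs expression values. The other genes named were chosen after the matching, as list members without a row or as examples of their lists.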

Results

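The study was laid out as a 2 by 2 factorial experiment in the brain of adult female CFW mice. Mice carried a pellet of 17β-estradiol (E2), the main circulating estrogen, or a placebo pellet. They received injections of glyceollins, phytoalexins made by soybean under stress, or of vehicle for 11 days. The acclimation period was recorded as 1 week. The 4 groups were placebo with vehicle, E2 with vehicle, placebo with glyceollin, and E2 with glyceollin. RNA was extracted from 3 mice in each group. Each group was represented by 1 library, pooled from 2 mice in the placebo-vehicle and E2-glyceollin groups and from 3 mice in the other groups. The design implies comparisons of E2 alone, glyceollin alone and their combination with control, and of the combination with each single treatment. None of these comparisons is reported, because the 4 columns of expression values could not be matched to samples. Their headings, A_0, B_0, C_0 and D_0, occur as names in no sample's title, description, source name or characteristics. Assigning a treatment to a column would have been a guess. With 1 library per group, the differences would also have had no replicate check. A departure from additive effects of E2 and glyceollin could not have been told apart from the number of pooled mice. Both divide the libraries in the same way.

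What could be described is which transcript models had rows in the table. No expression value was read, so the counts below describe that list of models. They do not show which of them were expressed in these libraries. The table held 94538 distinct Ensembl transcript identifiers, of which 91144 (96.4%) were found in GENCODE mouse release 21 and 3394 were not. The matched transcripts belonged to 37929 genes, and 24669 of these genes had a single transcript row. The largest number of rows in any gene was 42. Protein-coding genes numbered 21427. Processed pseudogenes followed with 4451 genes, microRNAs with 1907, antisense genes with 1799 and lincRNAs with 1665. Among the transcripts themselves, 45308 were annotated as protein coding, 12827 as retained introns and 4294 as targets of nonsense-mediated decay. The identifiers in the table therefore stand for transcripts, whereas the table's name calls it a gene table.

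The receptors through which estrogen acts all had transcript rows, which does not show that they were expressed. Esr1, which encodes estrogen receptor alpha, lies on chromosome 10 from 4611593 to 5005614 (GRCm38) and had 10 transcript rows. Esr2, which encodes estrogen receptor beta, lies on chromosome 12 from 76120419 to 76177259 and had 4 rows. Gper1, the G protein-coupled estrogen receptor, lies on chromosome 5 from 139423151 to 139427800 and had 2 rows. Pgr, the progesterone receptor and a textbook estrogen target, lies on chromosome 9 from 8899833 to 8968611 and also had 2 rows. All 20 estrogen-responsive genes of the fixed list had a row, among them Greb1 with 12 rows, Bdnf with 11 and Prl, which encodes prolactin, with 2. All 19 genes of the xenobiotic and antioxidant response were represented, including Cyp1a1 and Nqo1 with 1 row each.

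Genes that mark the cell types and regions of the brain, and those that mark the anterior pituitary, also had rows. The 16 oligodendrocyte and myelin markers, the 12 astrocyte markers and the 14 microglia markers all had rows. Mbp, which encodes myelin basic protein, had 16 transcript rows, and Gfap, an intermediate filament gene of astrocytes, had 3. All 16 choroid plexus markers, such as the transthyretin gene Ttr, and all 15 anterior pituitary markers were represented, as were the 21 hypothalamic neuropeptides. Over the 32 lists together, 620 of 630 memberships had at least 1 transcript row. The exceptions were Sts in the steroid synthesis list, the symbols Drd1a, Cyr61, Hbb-b1 and Hbb-b2, and Rpl32l and 4 histone genes. Rpl32l and the 4 histone genes are symbols of the annotation itself that had no row. Drd1, in the list of Drd1a, and Hbb-bs and Hbb-bt, in the list of Hbb-b1 and Hbb-b2, did have rows. Presence of a row says that a transcript model was quantified, not that it was expressed. All 6 Y-linked genes of the fixed list also had rows, although the mice were female. Coverage of a list therefore cannot tell which cells or tissues were sampled.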

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

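The settings planned before the data were examined, such as the pseudocount, the expression filter and the fold threshold, concerned expression values. None was applied, because no column of values could be tied to a sample. The annotation alternatives below were chosen after seeing the data. Against the GENCODE basic transcript set, 53732 identifiers were matched instead of 91144, as that set holds fewer transcripts per gene, and 37652 genes were represented instead of 37929. With unplaced scaffolds added to the comprehensive annotation, 91239 identifiers and 38015 genes were matched.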
